A study of Mus musculus with 24 samples.

How the data were processed

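RNA of the ventral midbrain was compared in 12 pools of mouse embryos, 3 at each of 4 stages a day apart from E10.5 to E13.5, against 1 RNA pool of adult ventral midbrain. Per the labels each pool combined 3 embryos, RNA was extracted with Trizol and RNeasy columns, amplified by T7 in vitro transcription with aminoallyl UTP, and coupled to Cy3 or Cy5. Each pool was hybridised with the dyes in both orders, so 24 arrays were used. Both arrays of a pool were averaged and counted as 1 replicate.

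The deposited scanner files hold the intensity of each spot in both channels as means, with the median and SD of the local background; per the file headers no background was subtracted. The scanner and its software are not given in the sources used here. The authors also deposited a table of normalized log2 ratios of embryo to adult. Its normalization method is not given in the sources used here. Against ratios computed from the scanner files its slopes were 0.982 to 1, and its column medians were −0.0178 to 0.0126. In 4 of the 12 pools the order of the dyes in the sample titles differs from the channel labels, and in these pools each column of deposited ratios matches the other array of the pair (r of the difference between arrays −0.985 or lower, against 0.973 or higher in the other 8). The channel labels were used here, and the mean of a pool is the same in either order.

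Each array held 45220 spots, of which 4046 were controls and 41174 probes. Background was corrected with the normexp method of limma (offset 50), and ratios were scaled within arrays by loess with control spots given no weight. A probe was kept if it lay more than 2 background SD above background with embryonic RNA on every array of any stage, or with reference RNA on at least 50% of the arrays, which left 38623 probes. Probe names came from a platform table, with 3726 symbols updated through a mouse gene table, after which 99.7% were current; 34186 probes had a gene name and 6988 did not. The probe with the highest mean signal stood for its gene, giving 17852 genes, of which 8555 had several probes. Signals over 60000 counted as saturated. R 4.3.3, limma 3.58.1 and data.table (1.17.8) were used.

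A linear model of limma with a mean for each stage was fitted to the 12 pools, with moderated variances (8 residual and 2.78 prior degrees of freedom) and Benjamini-Hochberg adjustment at 0.05. Comparisons were the 3 steps between neighbouring stages, E13.5 against E10.5, each stage and all pools against adult, and a moderated F test over the 4 stages. Errors of changes are standard errors of limma, and adjusted p-values of single genes are those of limma. The 34 gene lists, with 663 of 719 entries measured, were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation and the rotation test fry as alternatives. Lists, comparisons, thresholds and the rule for naming genes were chosen before the data were examined.

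Genes were named by rule. For E13.5 against E10.5 these were the 12 largest rises and 12 largest falls, and for each step the 6 largest of each, among genes that passed without overlap between the pools. Against adult they were the 8 largest of each, among genes above background in both channels with the same sign in every pool, and for the F test the 4 genes with the smallest p for each stage of highest mean. All members of the dopamine, floor plate and Onecut and Ebf lists could be named, from other lists the 3 largest rises and 3 largest falls of the window, and from the lists of adult glia and myelin the 3 genes farthest from adult. Only part of these are printed. Clone and predicted gene names were passed over.

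The method was tested on simulated data with 200 changed genes among 17852. For E13.5 against E10.5 it recovered 62.7% of changes of 0.5 log2 units, 94% of 1 and 100% of 2, and 7.07% of its calls were false. For the F test the shares were 58.2%, 92.5% and 100%, with 6.18% false. The simulated genes varied independently, and no pool was made to stand apart. Far more genes were called in the real data (7822 for E13.5 against E10.5), so these shares need not hold there. The median signal of embryonic RNA was 98.9 to 249 per array over a background of 38 to 42.5, which limits the precision for dim genes. Alternatives tried were no background correction, a normexp offset of 0, median centring, quantile scaling after loess, the authors' table, each dye order alone, a dye term with the pool as a random block, a replicate block, array weights, no probe filter and a stricter one, the mean over the probes of a gene, moderation with trend and robust variances, stricter thresholds, fits with only the stages compared, and leaving out each pool.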

Results

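Gene expression was measured in the ventral midbrain of mouse embryos, the tissue in which midbrain dopamine neurons are born, at 4 stages a day apart, from embryonic day E10.5 to E13.5. Each stage had 3 RNA pools, each combining the tissue of 3 embryos, so that 12 pools entered the comparisons. Every pool was hybridised to a dye-swapped pair of arrays, 24 in all, beside RNA pooled from adult ventral midbrain, and the pair was counted as 1 replicate. The median signal of the embryonic RNA ran from 98.9 to 249 per array over a background of 38 to 42.5, and 83.1% to 96.8% of the probes lay above background. For every gene named below as risen or fallen between stages, the 3 pools of the later stage all lay on that side of the 3 earlier ones. P-values measure the spread between these pools, and the number of pools, 3 per stage, limits the precision. The adult reference is 1 pooled RNA, whose own spread is left out of every comparison with it.

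The stages separated along the first principal component, which held 66.5% of the variance. Pools of the same stage correlated across genes at r = 0.94 to 0.991. The E10.5c pool lay farthest from the other pools of its stage, at r = 0.94 and 0.947, and 356 genes differed more than 2-fold from the mean of those pools. Relative to that mean its median over the pan-neuronal genes was 0.48 higher on the log2 scale, and its median over the mesenchyme genes was −0.715.

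**Figure D1:**
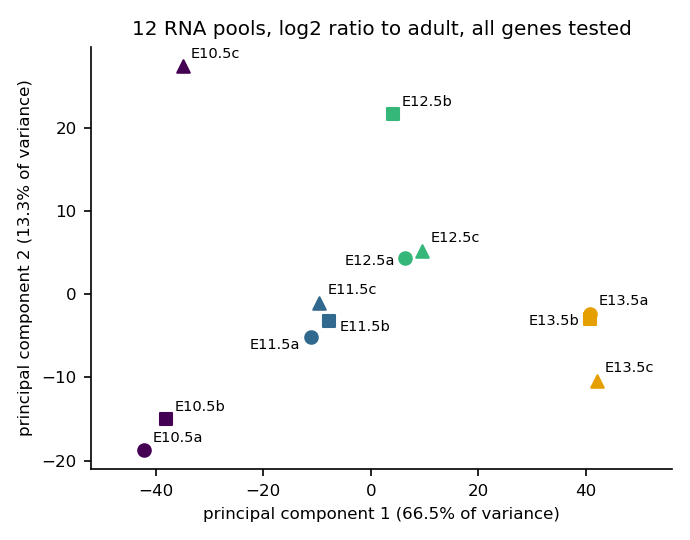
Each point is an RNA pool, placed by the first and second principal components of its log2 ratios to the adult reference, which hold 66.5% and 13.3% of the variance; colours mark stages and shapes mark the pools a, b and c. The first component runs from −42.1 for E10.5a to 42 for E13.5c, and E10.5c and E12.5b stand apart from the other pools of their stages on the second, at 27.4 and 21.6.

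The comparison of E13.5 with E10.5 asked how expression changed over the whole window. Chl1, a cell adhesion molecule of growing axons, rose by 4.63 ± 0.23 on the log2 scale (SE, 3 pools per stage, adjusted p = 8.08e-08), and Myt1l, a transcription factor of neurons, rose by 4.04 ± 0.10 (adjusted p = 2.38e-09). Mapt, which encodes tau, rose by 3.93 ± 0.25, the neuropeptide precursor Pmch by 3.91 ± 0.32, the bHLH factor Neurod6 by 3.47 ± 0.15 and the glycine receptor subunit Glra2 by 3.41 ± 0.089. Lum, a proteoglycan of connective tissue, fell by 3.72 ± 0.58 (adjusted p = 0.000327), as did the type I collagen chain Col1a1 (−3.12 ± 0.28) and Hmga2, a chromatin protein of early progenitors (−2.92 ± 0.089). Birc5, which acts in cell division, fell by 2.76 ± 0.066 (adjusted p = 2.38e-09). Fndc3c1 (−3.62 ± 0.15), the homeobox gene Nkx2-9 (−3.15 ± 0.16) and the blood cell gene Hemgn (−3.23 ± 0.26) fell as well. Ldha, which encodes lactate dehydrogenase, fell, with a change of −2.85 or lower, since its probe was saturated on 3 of the arrays of E10.5.

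Of 17852 genes tested with limma, 3725 rose and 4097 fell between E10.5 and E13.5, a total of 7822 after Benjamini-Hochberg adjustment, and 1666 of these changed at least 2-fold. At 2-fold the balance was the other way, with 914 up and 752 down. The 3 pools of one stage all lay beyond the 3 of the other for 9446 genes, or 52.9%, where chance gives 10%. Among the 4324 called genes with several probes, 308 had a probe that passed in the opposite direction.

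**Figure D2:**
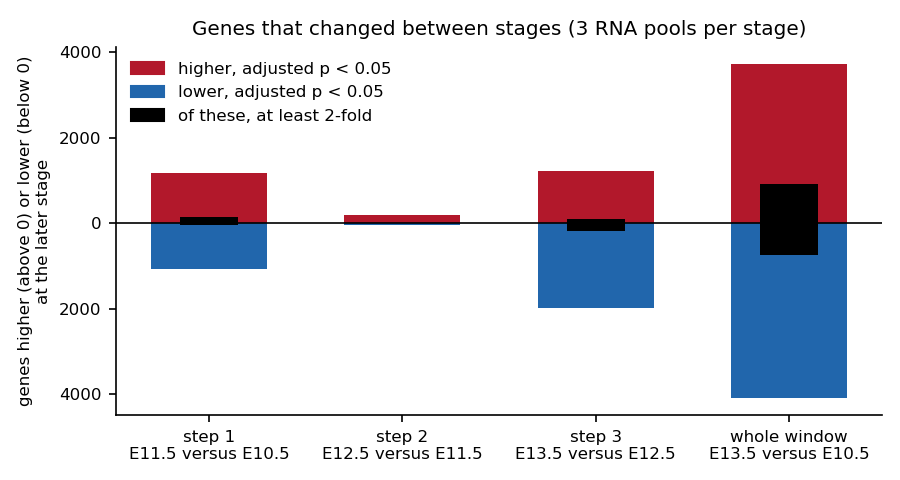
Bars give the number of genes that rose (above 0) or fell (below 0) at an adjusted p under 0.05 for each step of a day and for the whole window, with 3 RNA pools per stage; black bars give those that changed at least 2-fold. The counts were 1167 and 1085 for E11.5 versus E10.5, 189 and 54 for E12.5 versus E11.5, 1216 and 1993 for E13.5 versus E12.5, and 3725 and 4097 for the window.

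Of the 27 measured genes of the dopamine neuron list, 19 rose over the window, 1 fell and 7 did not pass, and the counts were equal when adjusted over the list alone. Nr4a2, a nuclear receptor required for the dopamine fate, rose by 1.85 ± 0.17 (SE, 3 pools per stage, adjusted p = 6.44e-06) on its brightest probe, while its 2 dimmer probes changed by −0.31 and −0.89 and passed in the opposite direction. The calcium-binding protein gene Calb1 rose by 1.64 ± 0.11 (adjusted p = 5.45e-07) and the neuropeptide gene Cck by 1.24 ± 0.11. Among the enzymes and transporters of dopamine, Ddc rose by 1.05 ± 0.091 (adjusted p = 4.01e-06), Th by 0.85 ± 0.15 (adjusted p = 0.000666) and the vesicular transporter Slc18a2 by 0.72 ± 0.10. The homeobox gene Pitx3 rose by 0.45 ± 0.098 (adjusted p = 0.00303). The dopamine transporter Slc6a3 rose by 0.46 ± 0.14 (adjusted p = 0.0189), a call lost without E10.5b (adjusted p = 0.0649), E13.5a (0.0579) or E13.5c (0.0734). En2 fell by 0.30 ± 0.11 (adjusted p = 0.0406), which was lost without any of E10.5a, E10.5b, E10.5c, E11.5c, E13.5a or E13.5c, at adjusted p = 0.0512 to 0.131, and with median centring (0.0696). Aldh1a1, Ret, Dlk1, Sncg, Kcnj6, Nxph3 and Slc6a2 did not pass, with changes between −0.09 and 0.16. As a group the list was higher than other genes (camera, adjusted p = 7.6e-06, and adjusted p = 0.037 with an estimated correlation).

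Floor plate and midbrain patterning genes moved in both directions over the window. Of 29 measured, 1 rose, 12 fell and 16 did not pass, with equal counts when adjusted over the list alone. The gene that rose was Lmx1a, a homeobox gene of the midbrain floor plate, by 1.04 ± 0.19 (SE, 3 pools per stage, adjusted p = 0.00105). Among those that fell were the secreted signals Shh (−1.17 ± 0.087, adjusted p = 1.29e-06) and Wnt5a (−1.44 ± 0.18, adjusted p = 6.22e-05) and the homeobox genes Nkx6-2 (−1.97 ± 0.17, adjusted p = 3.12e-06) and Otx2 (−0.90 ± 0.13, adjusted p = 0.000193). Foxa2 (−0.23 ± 0.12, adjusted p = 0.161) and Corin (0.11 ± 0.15, adjusted p = 0.59) did not pass. The list was lower than other genes (camera, adjusted p = 0.03), a call lost at adjusted p = 0.32 with an estimated correlation. It was lost without E13.5a as well (adjusted p = 0.078), where leaving out other single pools gave 0.014 to 0.039. Of the 7 Onecut and Ebf factors, Ebf3 rose by 1.66 ± 0.20 (adjusted p = 4.24e-05), Ebf4 fell and 5 did not pass, on the list alone as well. The fall of Ebf4, by 0.27 ± 0.081 (adjusted p = 0.0176), was lost without E10.5a (adjusted p = 0.0697), without E13.5a (0.0745) and with median centring (0.0505). That list was not called (camera, adjusted p = 0.72), and its median of −0.0054 and mean of 0.21 differed in sign. These values rest on single pools of E10.5: the median and mean were 0.42 and 0.46 without E10.5c, −0.20 and 0.070 without E10.5a, and −0.22 and 0.11 without E10.5b. The list was not called in any of these fits (adjusted p = 0.24 to 0.96).

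**Figure D3:**
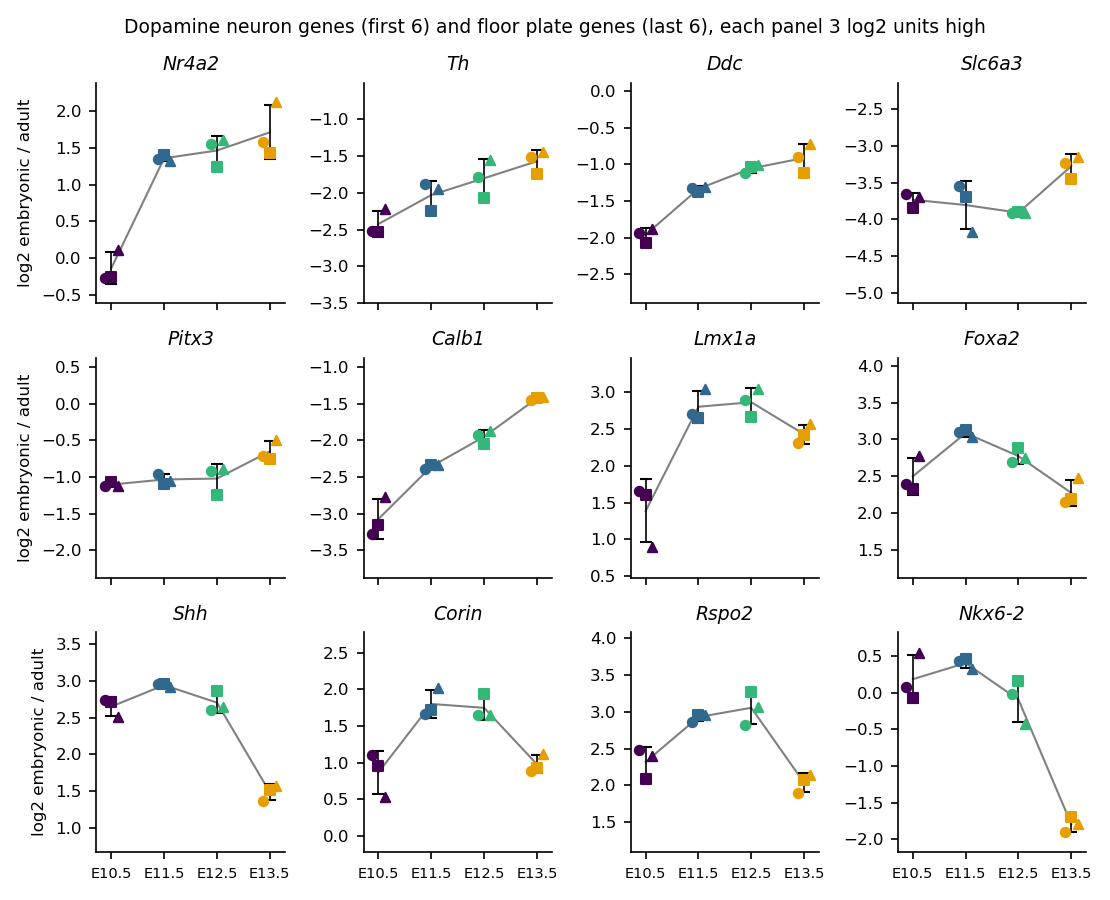
Log2 ratio to the adult reference of 6 dopamine neuron genes and 6 floor plate genes in each RNA pool (points; shapes mark the pools a, b and c) by stage, with lines through the means of 3 pools and bars of 1 SD; each panel spans 3 log2 units. Nr4a2 went from a mean of −0.14 at E10.5 to 1.36 at E11.5, and Shh went from 2.71 at E12.5 to 1.49 at E13.5.

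Cell cycle genes fell over the window. Of 44 measured, 43 fell, none rose and 1 did not pass, with equal counts on the list alone (camera, adjusted p = 7.6e-26, and adjusted p = 0.021 with an estimated correlation). Among them were the centromere protein Cenpa (−2.72 ± 0.17, SE, 3 pools per stage, adjusted p = 3.79e-07) and the replication helicase gene Mcm3 (−2.63 ± 0.14, adjusted p = 1.17e-07). Genes of the Lin28 pathway, which marks early developmental time, fell as well: 10 of 13 fell, none rose and 3 did not pass, and 11 fell when adjusted over the list alone (camera, adjusted p = 2.5e-06, and adjusted p = 0.021 with an estimated correlation). Lin28a itself fell by 2.44 ± 0.13 (adjusted p = 1.37e-07), and the RNA-binding protein gene Igf2bp1 fell by 2.20 ± 0.087. Ribosomal protein genes fell in 17 of 22 cases, none rose and 5 did not pass, on the list alone as well (camera, adjusted p = 2.6e-05, but adjusted p = 0.066 with an estimated correlation). Rps18 fell by 0.93 ± 0.14 (adjusted p = 0.000262).

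Of 28 pan-neuronal genes 26 rose over the window, none fell and 2 did not pass, also on the list alone (camera, adjusted p = 1.4e-12, but adjusted p = 0.067 with an estimated correlation). Of 27 synaptic vesicle genes 19 rose, none fell and 8 did not pass, and 21 rose when adjusted over the list alone (camera, adjusted p = 3.5e-08, but adjusted p = 0.066 with an estimated correlation). Rab3a, a GTPase of synaptic vesicles, rose by 2.39 ± 0.11 (SE, 3 pools per stage, adjusted p = 5.85e-08). Of 25 ion channel and receptor genes 19 rose, 2 fell and 4 did not pass, also on the list alone (camera, adjusted p = 5e-09, but adjusted p = 0.066 with an estimated correlation). The glutamate receptor subunit Gria2 rose by 3.06 ± 0.20 and the potassium channel Kcnd2 by 2.93 ± 0.14 (adjusted p = 8.15e-08). Axon guidance genes split, with 15 of 38 up, 8 down and 15 not passing, also on the list alone (camera higher, adjusted p = 0.01, but adjusted p = 0.18 with an estimated correlation). The Slit receptors Robo2 and Robo1 rose by 2.56 ± 0.15 and 1.61 ± 0.11, and the chemokine gene Cxcl12 fell by 1.76 ± 0.38 (adjusted p = 0.00317). Of 18 genes of GABAergic neurons 8 rose, 3 fell and 7 did not pass, also on the list alone (camera higher, adjusted p = 0.023, but adjusted p = 0.55 with an estimated correlation). Slc32a1, the vesicular GABA transporter, rose by 2.54 ± 0.18 (adjusted p = 8.21e-07). Helt, a factor of GABAergic progenitors, fell by 1.04 ± 0.19 (adjusted p = 0.00085). The E10.5c pool was 0.48 higher than the other pools of its stage over the pan-neuronal genes.

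Progenitor genes showed no common direction: of 25, 8 rose, 11 fell and 6 did not pass, also on the list alone (camera, adjusted p = 0.6). Slc1a3, a glutamate transporter of radial glia, rose by 2.03 ± 0.10 (SE, 3 pools per stage, adjusted p = 1.05e-07), while Nes, which encodes the filament protein nestin, fell by 1.50 ± 0.19 (adjusted p = 6.89e-05). Of 24 proneural and Notch genes 3 rose, 10 fell and 11 did not pass (camera, adjusted p = 0.14), or 4 and 12 on the list alone. The Notch target Hes5 fell by 1.79 ± 0.17 (adjusted p = 8.52e-06). Of 17 astrocyte genes 8 rose, 2 fell and 7 did not pass, or 9 and 2 on the list alone (camera higher, adjusted p = 0.016, but adjusted p = 0.2 with an estimated correlation). Aldh1l1, an astrocyte enzyme, rose by 2.04 ± 0.097 (adjusted p = 6.96e-08). The gap junction gene Gja1 fell by 1.91 ± 0.19.

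Of 24 Wnt targets and inhibitors 2 rose, 15 fell and 7 did not pass, or 2 and 16 on the list alone (camera, adjusted p = 0.00056, but adjusted p = 0.053 with an estimated correlation). The secreted inhibitor Sfrp2 fell by 1.85 ± 0.13 (SE, 3 pools per stage, adjusted p = 7.35e-07). Of 11 Hedgehog response genes 9 fell, none rose and 2 did not pass, also on the list alone (camera, adjusted p = 0.00015, but adjusted p = 0.066 with an estimated correlation). Gli3 fell by 1.71 ± 0.14 (adjusted p = 1.9e-06). Of 19 glycolysis and hypoxia genes 1 rose, 11 fell and 7 did not pass, also on the list alone (camera, adjusted p = 0.0068, but adjusted p = 0.55 with an estimated correlation). The hexokinase gene Hk2 fell by 2.45 ± 0.17 (adjusted p = 6.48e-07). The gene that rose was the phosphofructokinase Pfkp, by 1.13 ± 0.092 (adjusted p = 2.46e-06).

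Mesenchyme and pericyte genes fell on balance: 3 of 27 rose, 16 fell and 8 did not pass, or 3 and 17 on the list alone (camera, adjusted p = 0.0093, but adjusted p = 0.6 with an estimated correlation). Twist1, a transcription factor of mesenchyme, fell by 2.52 ± 0.26 (SE, 3 pools per stage, adjusted p = 1.49e-05). The pericyte genes Rgs5 and Abcc9 rose by 1.30 ± 0.097 and 0.95 ± 0.089. The E10.5c pool held less of the mesenchyme transcripts, with a median of −0.715 relative to the other pools of its stage.

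**Figure D4:**
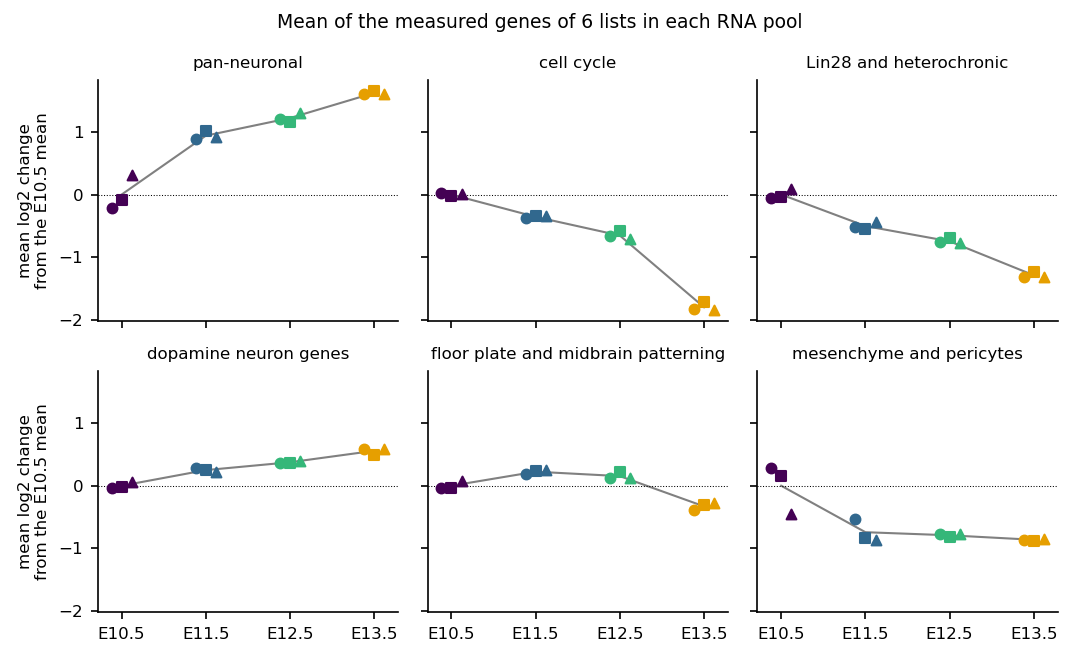
Mean over the measured genes of 6 gene lists in each RNA pool (points; shapes mark the pools a, b and c), in log2 units relative to the mean of the 3 pools of E10.5, by stage, with lines through the stage means. Over the window 26 of 28 pan-neuronal genes rose, 43 of 44 cell cycle genes fell, and 19 of 27 dopamine neuron genes rose.

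In the first step, from E10.5 to E11.5, the synaptic vesicle gene Syt4 rose by 2.48 ± 0.32 (SE, 3 pools per stage, adjusted p = 0.000886), Chl1 by 2.22 ± 0.23 and the neuropeptide gene Cartpt by 1.95 ± 0.090 (adjusted p = 5.83e-06). Nr4a2 rose by 1.50 ± 0.17 (adjusted p = 0.000556) and Ddc by 0.63 ± 0.091 (adjusted p = 0.00183). Of 27 dopamine neuron genes 5 rose, none fell and 22 did not pass, or 7 on the list alone (camera, adjusted p = 8.9e-05, but adjusted p = 0.053 with an estimated correlation). Of 29 floor plate and patterning genes 9 rose, none fell and 20 did not pass, or 11 on the list alone (camera, adjusted p = 0.0026, but adjusted p = 0.14 with an estimated correlation). Lmx1a rose by 1.42 ± 0.19 (adjusted p = 0.00119), the floor plate protease gene Corin by 0.93 ± 0.15 (adjusted p = 0.00286), Spon1 by 0.94 ± 0.13 and Slit2 by 0.57 ± 0.064 (adjusted p = 0.000546).

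Of 28 pan-neuronal genes 23 rose in this step, none fell and 5 did not pass, or 26 on the list alone (camera, adjusted p = 6.1e-19, but adjusted p = 0.053 with an estimated correlation). E10.5c stood 0.48 above the other pools of its stage over this list. Cell cycle genes fell in 22 of 44 cases, or 30 on the list alone, with none up (camera, adjusted p = 3.8e-13, but adjusted p = 0.053 with an estimated correlation). Lin28 pathway genes fell in 8 of 13 cases, or 9 on the list alone, with none up (camera, adjusted p = 1.7e-06, and adjusted p = 0.039 with an estimated correlation). Of 27 mesenchyme genes 2 rose and 14 fell, or 2 and 17 on the list alone (camera, adjusted p = 2.8e-06, but adjusted p = 0.23 with an estimated correlation); E10.5c lay at −0.715 there. Lum (−2.95 ± 0.58, SE, 3 pools per stage, adjusted p = 0.00815), Twist1 (−1.83 ± 0.26) and Gpc3, a cell surface proteoglycan (−1.91 ± 0.26, adjusted p = 0.00114), fell. In all, 1167 genes rose and 1085 fell, a total of 2252 by limma, and 28.2% of genes had no overlap between the stages where chance gives 10%. The total was 1260 without E11.5b, 1453 without E11.5c and 3134 without E10.5c (1772 up and 1362 down). It was 1375 with median centring (618 up and 757 down) and 1500 on the arrays with embryonic RNA in Cy5. With only these stages in the fit it was 1154, and with array quality weights, lowest for E10.5c at 0.156, it was 5142.

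From E11.5 to E12.5 few genes passed. Myt1l rose by 1.00 ± 0.10 (SE, 3 pools per stage, adjusted p = 0.00479), the homeobox gene Gbx2 by 1.08 ± 0.13 (adjusted p = 0.00604), Crym, which encodes a thyroid hormone binding protein, by 1.08 ± 0.12 (adjusted p = 0.00479) and Glra2 by 0.86 ± 0.089. Slc1a3 and Aldh1l1, genes of radial glia and astrocytes, rose by 0.99 ± 0.10 and 0.82 ± 0.097 (adjusted p = 0.00573). Each of these 6 genes passed whichever single pool was left out. Of 44 cell cycle genes 5 fell and none rose, or 19 on the list alone (camera, adjusted p = 4.1e-21, and adjusted p = 0.026 with an estimated correlation). Of 13 Lin28 pathway genes 3 fell and none rose, or 5 on the list alone (camera, adjusted p = 3.6e-07, and adjusted p = 0.023 with an estimated correlation). By limma no gene of the dopamine list or of the floor plate list passed, and at an unadjusted p under 0.05 the counts were 7 up and 0 down of 27, and 0 up and 6 down of 29. The floor plate list was lower than other genes (camera, adjusted p = 0.019, but adjusted p = 0.45 with an estimated correlation).

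In this step 189 genes rose and 54 fell, a total of 243 by limma, and 24.9% of genes had no overlap between the stages where chance gives 10%. The 6 largest falls were in H2ac18, H2ac10, H2ac15, H2aj and H2ac20, histone genes with near-identical copies, and in the metallothionein gene Mt2, from −1.23 ± 0.20 for H2ac18 (SE, 3 pools per stage, adjusted p = 0.0189) to −0.94 ± 0.19 for H2ac20 (adjusted p = 0.0447). Every one of these falls lost its call without E11.5a, where the 6 adjusted p-values ran from 0.0871 for H2ac18 to 0.17 for H2ac20. H2ac18 lost its call without E11.5b too (0.0749), and H2aj without E11.5b (0.0744) or E11.5c (0.053). H2ac10 lost it without E11.5b, E11.5c or E12.5a (0.0552 to 0.0827), H2ac15 without these or E12.5b (0.0641 to 0.105), Mt2 without E11.5c or any pool of E12.5 (0.0638 to 0.0997), and H2ac20 without any pool except E10.5a and E10.5c (0.0538 to 0.17). Leaving out a single pool moved the total to 35 (E11.5a), 60 (E11.5b), 50 (E11.5c), 101 (E12.5a), 59 (E12.5b), 56 (E12.5c), 153 (E13.5a), 146 (E13.5c) or 1366 (E10.5c). Pools of E10.5 and E13.5 are not part of this step. Leaving one out changes only the spread shared by all stages and its degrees of freedom, not the size of any change here. The total of 243 thus depends on the spread that E10.5c adds. The total was 40 and 145 on the arrays with embryonic RNA in Cy5 and in Cy3, 807 with a dye term and 153 with the replicate block. It was 646 with only these stages in the fit and 1124 with array quality weights. With median centring 258 genes rose and 22 fell.

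From E12.5 to E13.5 Pmch, the precursor of a hypothalamic neuropeptide, rose by 3.22 ± 0.32 (SE, 3 pools per stage, adjusted p = 7.44e-05), Neurod6 by 2.88 ± 0.15, Plppr4 by 2.09 ± 0.15 and Glra2 by 1.83 ± 0.089 (adjusted p = 3.65e-06). Nkx2-9 fell by 2.11 ± 0.16, and so did the cell division genes Birc5 (−1.78 ± 0.066, adjusted p = 5.33e-07), Aurkb (−1.74 ± 0.15) and Cdc20 (−1.72 ± 0.12). Of 29 floor plate and patterning genes 14 fell, none rose and 15 did not pass, or 16 on the list alone (camera, adjusted p = 2e-06, but adjusted p = 0.055 with an estimated correlation). Those that fell included Shh (−1.22 ± 0.087, adjusted p = 9.75e-06), Nkx6-2 (−1.70 ± 0.17), the Wnt agonist Rspo2 (−1.02 ± 0.13, adjusted p = 0.000319), Slit2 (−0.77 ± 0.064) and Corin (−0.77 ± 0.15, adjusted p = 0.00469). Of 27 dopamine neuron genes 8 rose, 2 fell and 17 did not pass, or 9 and 2 on the list alone (camera, adjusted p = 0.00016, but adjusted p = 0.055 with an estimated correlation). Slc6a3 rose by 0.63 ± 0.14 (adjusted p = 0.00868), Calb2 by 0.82 ± 0.098 and Cck by 0.59 ± 0.11.

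Of 44 cell cycle genes 42 fell in this step, none rose and 2 did not pass, also on the list alone (camera, adjusted p = 1.6e-36, and adjusted p = 0.0087 with an estimated correlation). Of 24 proneural and Notch genes 13 fell and none rose, or 14 and 1 on the list alone (camera, adjusted p = 0.00014, but adjusted p = 0.24 with an estimated correlation). Hes5 (−1.31 ± 0.17, SE, 3 pools per stage, adjusted p = 0.000446) and Notch3 (−1.07 ± 0.21) were among those that fell. Of 25 ion channel and receptor genes 15 rose and none fell, also on the list alone (camera, adjusted p = 2.3e-10, but adjusted p = 0.055 with an estimated correlation). In all 1216 genes rose and 1993 fell, a total of 3209 by limma, with no overlap between the stages for 39.7% of genes where chance gives 10%. With median centring 704 rose and 2095 fell.

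A moderated F test over the 4 stages asked which genes differed anywhere in the window, and it passed 6714 genes. Means were highest at E10.5 for 2946 of them and at E13.5 for 2837, against 361 at E11.5 and 570 at E12.5. The mean rose at every step for 2226 genes, or 33.2%, and fell at every step for 1996, or 29.7%, where any given order of 4 stages takes 4.17% by chance. Hmga2 fell from 5.05 ± 0.20 (SD, 3 pools, log2 ratio to adult) at E10.5 to 2.14 ± 0.055 at E13.5 (adjusted p = 5.72e-08), and Nmnat2, which maintains axons, rose from −2.88 ± 0.023 to −0.41 ± 0.015 (adjusted p = 1.65e-08). Among genes with their highest mean between the ends of the window, Jam3 went from 0.68 ± 0.051 at E10.5 to 0.90 ± 0.072 at E11.5 and −0.13 ± 0.051 at E13.5 (adjusted p = 8.54e-07). Cartpt went from −3.50 ± 0.18 at E10.5 to −0.96 ± 0.012 at E12.5 and −2.27 ± 0.12 at E13.5 (adjusted p = 1.22e-07).

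Against the adult reference Mest, an imprinted gene of embryonic growth, was 5.25 ± 0.041 higher on the log2 scale (SE, 12 pools, limma adjusted p = 8.46e-16), the neuronal progenitor factor Sox11 was 5.00 ± 0.047 higher and the embryonic globin Hba-x 4.82 ± 0.035 higher. The myelin protein gene Mbp stood at −6.02 or lower and the astrocyte gene Sparcl1 at −6.10 or lower, both being bounds because their probes were saturated with reference RNA on 13 and 21 of the 24 arrays. The neurofilament gene Nefh stood at −5.38 ± 0.055 and Thy1, a surface protein of mature neurons, at −5.50 ± 0.039. Each of these genes had the same sign in 12 of 12 pools.

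At E13.5 all 17 astrocyte genes lay below adult, also on the list alone (camera, adjusted p = 6.7e-09, and adjusted p = 0.044 with an estimated correlation). So did all 15 genes of oligodendrocytes and myelin (camera, adjusted p = 3.2e-09, but adjusted p = 0.081 with an estimated correlation) and 19 of 20 microglia genes (camera, adjusted p = 2.8e-06, but adjusted p = 0.081 with an estimated correlation), with equal counts on the lists alone. Gfap, a filament protein of astrocytes, was above background on 14 of the 24 arrays in the embryonic channel. Of 27 dopamine neuron genes 20 were below adult at E13.5, 6 above and 1 did not pass, also on the list alone (camera, adjusted p = 0.0069, but adjusted p = 0.13 with an estimated correlation). Slc6a3 stood at −3.27 ± 0.16 (SD, 3 pools, limma adjusted p = 1.63e-10), Aldh1a1 at −3.12 ± 0.13 and Th at −1.57 ± 0.16, while Nr4a2 stood at 1.71 ± 0.37 and Dlk1 was 1.84 above adult. Of 29 floor plate and patterning genes 17 were above adult and 6 below, also on the list alone (camera, adjusted p = 0.0027, but adjusted p = 0.13 with an estimated correlation). Otx2 stood at 2.84 and Shh at 1.49 ± 0.11. In all 15125 genes differed from the reference over the 12 pools, 6975 higher and 8150 lower, and 3411 of them at least 2-fold.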

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

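The probe filter against control spots, the fits without both E10.5c and E12.5b, and the median centring of gene lists were chosen after seeing the data. Genes passing from E10.5 to E11.5 (2252) came to 1375 with median centring (618 up and 757 down, against 1167 and 1085), 1500 with embryonic RNA in Cy5, 5142 with array weights, 1154 with only the stages compared, 174 at 2-fold, 934 at an adjusted p under 0.01 and 3710 excluding both E10.5c and E12.5b. From E11.5 to E12.5 (243) they came to 40 in Cy5, 145 in Cy3, 807 with a dye term and the pool as random block, 153 with the replicate block, 1124 with array weights, 646 with only the stages compared, 11 at 2-fold, 24 at 0.01 and 892 excluding both pools. At 2-fold the other counts were 286 from E12.5 to E13.5 (1697 at 0.01), 1666 for the window (914 up and 752 down), 3411 against adult and 1679 for the F test. Stricter thresholds give fewer by construction. For the step from E11.5 to E12.5, leaving out a pool of E10.5 or E13.5 can act only through the shared spread and its degrees of freedom. For the other alternatives the cause was not tested. With median centring the step to E12.5 had 258 genes up and 22 down, and the step to E13.5 704 up and 2095 down. Leaving out 1 pool gave 1260 to 3134, 35 to 1366 and 2151 to 4687 for the 3 steps, 6726 to 8346 for the window, 14824 to 15277 against adult, 5547 to 8235 for the F test, and 14 to 16 lists against 15. Only 3 lists were called with an estimated correlation, 22 with fry and 17 with median centring. Msx1 against adult reversed with median centring, from −0.21 to 0.0253. No background correction, an offset of 0, the other probe filters, the mean over probes, trend and robust moderation and the authors' table left each count of genes within 1.5 times; of these, gene lists were run only with no background correction, the mean over probes and the authors' table, and their number stayed within 1.5 times; quantile scaling after loess leaves ratios as they are by construction. Of 1101 results on named genes, 973 kept direction and call with median centring (38 lost the call, 13 gained one). The count was 1069 both with the authors' table (6 and 9) and with the replicate block (21 and 11). Excluding both pools it was 923 (10 and 100). The size of the changes was not compared. Signal over background limits dim genes. A slide or scan block was not run, because the files give no slide or scan date.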

Other observations

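Lists outside the report were read over the window from E10.5 to E13.5 with the same tests. Among 16 red blood cell genes 2 rose, 10 fell and 4 did not pass (camera, adjusted p = 0.059). The list was called as lower without E10.5c (0.0029), without E11.5b (0.049) and with median centring (0.038), and leaving out other single pools gave 0.058 to 0.18. The adult globins Hbb-b2 and Hbb-b1 rose by 2.65 ± 0.15 and 2.22 ± 0.20 (SE, 3 pools per stage, limma adjusted p = 2.05e-07 and 4.89e-06). These are near-identical copies. The embryonic globins Hbb-bh1 (−1.57 or lower, as it was saturated on 2 arrays of E10.5) and Hba-x (−1.12 ± 0.098) fell. Among 20 microglia and macrophage genes 4 rose, 3 fell and 13 did not pass (camera, adjusted p = 0.89; median −0.0533, mean 0.00215). The microglial receptor P2ry12 rose by 1.18 ± 0.064, and the macrophage receptor Mrc1 fell by 1.30 ± 0.31. Among 24 endothelial genes 3 rose, 5 fell and 16 did not pass (camera, adjusted p = 0.4), with Cldn5 up at 0.56 ± 0.15 and Cdh5 down at −0.93 ± 0.16. Neural crest and placode genes gave 1 rise and 4 falls of 11 (camera, adjusted p = 0.4), with Snai2 at −1.19 ± 0.13. Skeletal muscle genes gave 1 rise and 3 falls of 15 (camera, adjusted p = 0.6). Oligodendrocyte and myelin genes gave 1 rise of 15 (camera, adjusted p = 0.72; median −0.0241, mean 0.029). Oligodendrocyte precursor genes gave 1 rise and 3 falls of 10 (camera, adjusted p = 0.7), with Lhfpl3 at 1.13 ± 0.12 and Pdgfra at −1.65 ± 0.36.

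Among neuronal and regional lists, 5 of 9 on the list of oculomotor and other motor neurons rose and none fell (camera, adjusted p = 0.071). That list was called as higher without E13.5b (0.039) and with median centring (0.04), and leaving out other single pools gave 0.063 to 0.096. Of these 5, Slc6a4 and Tph2, at 1.24 ± 0.16 and 1.21 ± 0.17 (SE, 3 pools per stage), are serotonergic genes, so the count does not show a rise of motor neuron genes as a group. Isl1 stood at 1.17 ± 0.20, and Slc5a7 and Prph, named after their values were seen, at 0.73 ± 0.14 and 0.37 ± 0.078. The motor neuron genes Chat (−0.0097 ± 0.062), Phox2a (−0.24 ± 0.11) and Mnx1 (−0.11 ± 0.067) did not pass. Of 12 glutamatergic and red nucleus genes 3 rose and 3 fell (camera, adjusted p = 0.64); the vesicular glutamate transporter Slc17a6 rose by 1.98 ± 0.16 and Isl2 fell by 1.32 ± 0.16. Of 12 hindbrain Hox and neighbouring genes 1 rose, Gbx2 at 1.60 ± 0.13, and 2 fell (camera lower, adjusted p = 0.6; median −0.127, mean 0.0201). Of 17 forebrain genes 3 rose and 3 fell (camera higher, adjusted p = 0.99; median −0.0169, mean 0.0135), with Fezf1 at −1.49 ± 0.25. Of 15 genes of diencephalon and pretectum 5 rose and 3 fell (camera higher, adjusted p = 0.51; median −0.00624, mean 0.245), with Lhx9 at 1.73 ± 0.27. Single pools carry these small values. Without E10.5c the mean was 0.435 for diencephalon and pretectum, 0.14 for forebrain, 0.04 for hindbrain Hox, −0.0156 for microglia and −0.00165 for oligodendrocytes. Over all pools left out in turn the means ran from 0.136 to 0.435, from −0.0533 to 0.14, from 0.00673 to 0.04, from −0.0238 to 0.0391 and from −0.00674 to 0.0877. None of these lists was called in any of these fits, where the lowest adjusted p was 0.14. Of 12 imprinted growth genes 2 rose and 7 fell (camera, adjusted p = 0.27), with Ndn at 1.79 ± 0.16 and Mest at −1.83 ± 0.12. Oxidative phosphorylation gave 2 rises and 1 fall of 19, and 0 and 0 when adjusted over the list alone (camera, adjusted p = 0.51). Cholesterol synthesis gave 3 rises and 5 falls of 15 (camera higher, adjusted p = 0.97; median 0.0837, mean −0.009, which ran from −0.0446 without E10.5c to 0.0216 without E10.5b), and stress and immediate early genes 1 rise and 6 falls of 16 (camera, adjusted p = 0.43). Gene families grouped by name were tested only after the results were seen, 232 with at least 10 genes. Camera called 26, 10 higher and 16 lower, and none with an estimated correlation, where the lowest adjusted p was 0.39. The clustered protocadherins Pcdhb, near-identical copies, rose in 17 of 21 cases (median 0.65, but 1.22 with an offset of 0) and the Camk kinases in 9 of 10 (median 0.80). The Mcm helicase genes fell in 9 of 10 cases (median −1.79), as did the near-identical H2ac histone genes (median −1.83). Each of these medians kept its sign under the scaling alternatives.

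The tests of later embryos, of the covariance between probes, and of other splits for the steps, the window and the gene lists were chosen only after the result was seen, and the bounds for reading the probe correlation and the hypothalamus list were changed after it. The E10.5c pool stands apart from E10.5a and E10.5b. Its deviation from the stage mean correlated at 0.335 with that of E12.5b, the highest value among pairs of pools from different stages. E12.5b stood at 0.0361 over the placenta and decidua genes tested next. What these pools share was not tested. Placenta and decidua genes that had not been looked at when the pattern was found were higher in E10.5c. Their median was 0.356 over 23 genes (22 above 0). That lay above the central 95% of 10000 lists matched on signal, whose upper end was 0.131. Some of these genes belong to families of genes seen beforehand, such as Gzmd, Gzme and Gzmg beside Gzmc. Genes of a family can move together, which the random lists do not allow for. RNA of placenta or decidua may be part of the cause, but this test does not settle it. Of 54 genes on the placenta and decidua list 41 were measured, all above background elsewhere in these arrays and 2 on other lists. Prl8a2, Afp and Plac8, seen beforehand, were higher by 3.91, 2.31 and 2.30. Among the unseen Hoxa10 was higher by 1.21, Tpbpa by 0.36, and Tfpi stood at −0.964.

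Later embryos in the E10.5c pool would lower its cell cycle genes to −0.152, given the pan-neuronal shift of 0.479. Their median was 0.105 (95% interval −0.011 to 0.183). That interval resamples genes within 1 pool and leaves out the spread between pools. Other pools deviated from those of their stage by −0.102 (E12.5c) to 0.138 (E12.5b) over this list, so the test does not decide. The higher pan-neuronal and lower mesenchyme medians of E10.5c went in the direction of the step to E11.5. Failed single probes would leave probes of a gene uncorrelated. The correlation of 0.174 lay under the bound set beforehand, yet the 9 later pools gave 0.0972 to 0.187, so that test cannot tell failed probes from a small shift. The covariance of 0.031 (95% interval 0.0264 to 0.0358) lay above 0.00147 to 0.00905 in those pools, which argues against failed probes as the whole cause. Less mesenchyme in the dissected tissue, a median of −0.715 in E10.5c, stays open and was not tested. Apart from RNA of placenta or decidua and later embryos, no biological explanation was tested.

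Pmch stood at −4.70, −4.01 and −0.79 relative to adult at E10.5, E12.5 and E13.5, and hypothalamic tissue in the E13.5 pools could raise it. The median step from E12.5 to E13.5 over 15 hypothalamic genes not seen before was −0.0825, with 5 above 0. That value met the bound set beforehand (at or below the matched median of −0.03), but it lies at the 12.3rd percentile of matched lists, within their spread, so it does not decide. Of 33 genes on that list 29 were measured, 12 of them on other lists. All 29 lay above background on most arrays outside E10.5c, which include those of E12.5 and E13.5. Relative to adult at the same stages, Nkx2-1 stood at 2.59, 3.07 and 2.61 and Dlx2 at 3.28, 3.52 and 3.65. Others did not stand above adult in this way, such as Bsx (0.029, 0.064 and 0.117) and Sst (−2.26, −0.354 and −0.437). Whether the pools of all stages held hypothalamic tissue was not tested. Hcrt (−0.38), Hmx3 (−0.46) and Hdc (−0.24) fell from E12.5 to E13.5. Hypothalamic tissue and a rise within the midbrain cannot be told apart here.

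Other splits of the same pools were counted. Each comparison of 3 against 3 pools has 10 splits, too few for a share under 0.05. In 1 split, the real one, the count was as large: 2252, 243 and 3209 genes for the steps and 7822 for the window. The highest of the others was 0 each time. Every other split mixes the stages compared, which puts their difference into the spread and lowers the count of genes. The counts of 0 are therefore not evidence against chance. For gene lists 3 of the 10 splits called as many, 15 in the real split and 15 as the highest other. The other splits called 6 to 15 lists, so the number of lists called by camera does not set the real split apart. A mixed split can keep part of the stage difference, so these counts do not give the number expected by chance either. For the F test 100 draws were counted and 1, the real one with 6714 genes, was as large. The highest other had 5464. A share of 1 in 100 lies under the bound of 0.05 set beforehand, which argues against chance for the F test as a whole. It is the smallest share that these draws can give, so it gives no finer measure and says nothing about single genes.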
